A study of Oryza sativa with 9 samples.

How the data were processed

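Gene expression was measured on 9 1-colour Affymetrix rice arrays, 3 each for whole seedlings, mature pollen and isolated sperm cells of field-grown wild-type *Oryza sativa* ssp. japonica, cultivar Katy. Per the labels, total RNA was purified on columns and amplified in a 2-cycle cDNA protocol before biotin-labelled cRNA was hybridised. The labels state an input of 100 ng of total RNA for pollen and seedling and state none for sperm cells. Such amplification copies from the 3′ end of a transcript, so probe sets far from that end read low, and unequal input can change the spread between arrays.

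The table deposited by the authors holds 1 signal intensity per probe set and array, in linear units, made with MAS5 per the submitters' processing notes, with no version given in the sources used here. MAS5 combines perfect-match and mismatch probes into 1 value and scales each array as a whole. The 2% trimmed mean of the signals lay between 500.1 and 500.2 on every array, so the arrays were taken at the authors' scaling. Such scaling sets the average of each array equal and cannot show a change in the total amount of RNA per cell. Detection calls were not used here. The number of arrays limits the precision.

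Of 57381 probe sets, 123 array controls were left out and 57258 were tested. Gene identities came from a platform annotation of 2016, which listed 1 gene for 22436 probe sets, several genes for 95 and none for 34727. All 17905 genes with a probe set were found by identifier in a gene table of assembly ASM3414082v1, and 2448 of them carried a name other than a locus number. The genome build of the array design was not given in the sources used here, so no coordinates are printed. Names are those of the annotation, and distinct loci can share 1 name.

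Signals were put on a log2 scale after adding a pseudocount of 4.47, the 10th percentile of all signals. Group means were fitted with limma 3.58.1 (lmFit, contrasts and eBayes with a trend) in R 4.3.3, with all 9 arrays sharing 1 estimate of the spread. Each contrast was tested two-sided and adjusted by Benjamini-Hochberg over 57258 probe sets. A probe set was called higher or lower at an adjusted p under 0.05 and a change of at least 2-fold. A background limit of 97.1 was taken as the 95th percentile of 23 control probe sets with no rice target. Where the dimmer group lay under this limit, the ratio of the brighter group's mean to the limit is given as "at least N-fold", which describes the signals and is not a test. Otherwise the fold is the ratio of mean signals. Errors of signals are SD over 3 arrays, and errors of log2 changes are SE from the fit.

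Replicate numbers were checked as a possible pairing. The correlation of array deviations between arrays of equal number lay between −0.00604 and 0.00836 across probe sets, so the numbers were not used to pair samples in the reported fit. A fit with replicate number as a block gave 10883 probe sets higher and 14019 lower in sperm than in seedling, 14546 and 13301 for pollen against seedling, and 9632 and 12808 for sperm against pollen. With the block, 5883 probe sets were higher in sperm than in both others and 7186 higher in pollen than in both others. It gave 5517 probe sets higher and 9777 lower than seedling in both pollen and sperm, and 17 list calls.

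Gene lists were tested with limma's camera, with a preset correlation of 0.01 and, as an alternative, an estimated one, adjusted over 99 tests of 33 lists and 3 contrasts. Camera compares a list with the other genes. Each gene was represented by its probe set with the highest mean log2 value. Lists had been planned from gene descriptions. Since the annotation holds symbols, the lists were rewritten as symbol patterns before any comparison of expression, and 9 lists were added at that point: cellulose and glucan synthesis, potassium transport, homeobox and WOX factors, auxin signalling, jasmonate signalling, phosphatase 2C, kinesins, zinc finger CCCH proteins and autophagy. The other lists were histones, small RNA pathway, DNA methylation, histone modifiers, cell cycle, DNA replication, DNA repair, proteasome, ubiquitin conjugation, cytosolic ribosomal proteins, photosynthesis, expansins, actin cytoskeleton, tapetum and anther wall, calcium signalling, small GTPase signalling, vesicle trafficking, heat shock proteins, aquaporins, lignin and phenylpropanoid, sugar transport and starch, and MADS-box, MYB and WRKY factors. The planned pattern for gamete fusion genes matched no symbol, so that list was not tested; HAP2A and HAP2B, whose symbols resemble a name in that pattern, are reported under the rule for named genes. For want of matching symbols, no test was made of the planned lists of F-box proteins, plastid ribosomal proteins, pectin modification, RALF peptides, the respiratory chain and transposons. Matching by symbol limits list members to the 2448 named genes, while camera compares them with all other genes. Named genes were 1091 of 6687 genes higher in seedling than in both others. They were 310 of 2769 such genes for sperm and 298 of 2215 for pollen. Whether this moved the list tests was not tested.

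The genes named were set by rule before the data were examined: for each contrast and direction, and for both preferential sets, the 10 named genes with the largest change among those past the threshold whose arrays did not overlap between groups. Probe sets whose suffix marks possible cross-hybridisation were left out of this rule. For each list called, up to 4 members with the largest change could be named. An informative symbol took the place of the description in the rule. Examples from lists that were not called were dropped after 18 of their changes were seen to turn sign under an alternative scaling; the counts of these are given with the alternatives. Members of such lists are named only where the rule for the 10 largest changes names them.

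The fit was tested on simulated data of 57258 probe sets, a small part of which was given a change. In each contrast 67, 67 and 66 probe sets were given log2 changes of 1.5, 2 and 3. They were drawn from probe sets with a seedling mean above the median. With so few changed, the adjusted threshold is stricter than in the data, where 39.9% to 49.3% of probe sets were called. The shares recovered therefore do not give the sensitivity of the reported fit. For sperm against seedling, it recovered 19.4% of changes of 1.5 on the log2 scale, 46.3% of changes of 2 and 74.2% of changes of 3, with 5 calls among unchanged probe sets. For pollen against seedling, the shares were 16.4%, 43.3% and 74.2%, with 6 such calls. For sperm against pollen, they were 14.9%, 46.3% and 78.8%, with 1 such call. A list shifted by 1 on the log2 scale in a simulation of 17905 genes was called in 2 of 2 tests, and 0 of 97 other list tests were called. The list was calcium signalling, with 88 genes. All other genes were left unchanged and all were drawn independently with 1 common spread. These counts therefore do not give the rate of false or missed list calls in the data, where lists are smaller, members can correlate and many genes change.

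Alternatives chosen before the data were examined were no pseudocount, a pseudocount 4 times as large, quantile normalization, scaling to the same median, scaling by ribosomal protein probe sets, a filter on low means, the replicate block, only the 6 arrays compared, no trend, no cross-hybridising suffixes, and leaving out each replicate in turn. For lists, the estimated correlation and the mean of all probe sets of a gene were added to these. Scaling by hybridisation controls, a filter at the background limit, and the cytosolic ribosomal protein list and its scaling without CL18 and CL27, symbols that name plastid proteins, were chosen after seeing the data. The other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.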

Results

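Transcripts of mature pollen and of isolated sperm cells, both collected at anthesis, were compared with those of whole rice seedlings, which served as the sporophytic reference. Sperm cells are the male gametes carried inside the pollen grain, whose remaining volume is the vegetative cell that grows the pollen tube. Seedlings were taken when the collar of leaf 3 had formed and held shoots, leaves, roots and apices. Each group had 3 arrays, named biological replicates in the labels. Arrays of 1 group correlated across probe sets at Pearson r of 0.953 to 0.956 in seedling, 0.894 to 0.902 in pollen and 0.920 to 0.927 in sperm. Pollen and sperm arrays correlated at 0.634 to 0.651, seedling and sperm at 0.524 to 0.547, and seedling and pollen at 0.479 to 0.490. Probe sets are not independent replicates. The first principal component, with 53.7% of the variance, set seedling apart from both male samples, and the next, with 30.9%, set pollen apart from sperm.

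Signal over background differed between groups. The share of probe sets above the background limit was 39.96% ± 0.24 (SD, n = 3) in seedling, 40.2% ± 0.80 in pollen and 31.5% ± 1.29 in sperm. The 100 brightest probe sets took 7.46% ± 0.48 of the signal in seedling, 12.8% ± 0.78 in pollen and 8.35% ± 0.085 in sperm. Control transcripts added before hybridisation averaged 3367 ± 367 in seedling, 9220 ± 340 in pollen and 6145 ± 1800 in sperm. The 3′ to 5′ ratio of actin was 19.0 ± 0.70 in seedling, 4.99 ± 0.95 in pollen and 58.9 ± 16.7 in sperm. That of ubiquitin was 1.05 ± 0.059, 1.91 ± 0.35 and 1.79 ± 0.20, and that of the glyceraldehyde phosphate dehydrogenase gene 44.1 ± 7.09, 57.1 ± 17.1 and 23.3 ± 5.46, with a 5′ signal under the background limit in sperm, so the 3 ratios ordered the groups differently. The signal of 25S ribosomal RNA was 7562 ± 485, 7822 ± 755 and 1367 ± 274. These measures of RNA and labelling therefore changed with the groups compared below.

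Sperm cells were first compared with seedlings, to describe the male gamete against a sporophytic tissue. HAP2A (LOC4338255), for which the annotation gives a symbol and no description, had a mean signal of 58140 ± 3198 (SD, n = 3) in sperm and 63.0 ± 4.71 in seedling. It was at least 599-fold higher in sperm, a log2 change of 9.75 ± 0.14 (SE, adjusted p = 1.48e-13). HAP2B (LOC4347632) was 163-fold higher. JMJ705, a histone H3 lysine demethylase, was 316-fold higher and the NIMA-related kinase NEK1 277-fold. The starch synthase SSII-3, the mitogen-activated protein kinase MPK17, the β-expansin EXPB9, the argonaute AGO14, the kinase WNK6 and RRA19 completed the 10 named genes with the largest increase, each at least 44.8-fold higher. In the other direction, LHCP, a light-harvesting chlorophyll a/b protein, had a signal of 34984 ± 3080 in seedling and 2.39 ± 0.80 in sperm, at least 360-fold lower in sperm (log2 change −12.32 ± 0.52, adjusted p = 3.47e-10). The Rieske protein gene petC, the photosystem I subunit PSAH and the Rubisco activase rcaA1 were at least 312-, 125- and 290-fold lower. BURP2, the homeodomain factor Hox16, the metallothionein MT-1-4b, the plastid superoxide dismutase sodCp, the nicotianamine synthase NAS2 and 2-HPCL were at least 124-fold lower.

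The small RNA pathway, DNA replication and histone lists stood higher in sperm than other genes did, while histone modifiers (adjusted p = 0.597), DNA methylation (adjusted p = 0.0975) and DNA repair (adjusted p = 0.0537) were not called. Of 26 small RNA pathway genes, 15 were higher in sperm and 6 lower (camera, adjusted p = 0.00296 with the preset correlation and adjusted p = 0.297 with an estimated correlation). AGO14 and AGO17 were at least 44.8- and 60.1-fold higher, the germline argonaute MEL1 at least 19.1-fold, and AGO2 27.7-fold. Of 30 DNA replication genes, 15 were higher and 7 lower (adjusted p = 0.00464, and adjusted p = 0.211 with an estimated correlation). The replication protein A subunits RPA32C and RPA70c were 61.6- and 40.7-fold higher and the origin recognition subunit ORC3 53.5-fold. PCNA, the sliding clamp of the replication fork, went the other way and was at least 41.0-fold lower. Of 6 histone genes, 4 were higher and none was lower (adjusted p = 0.0175, and adjusted p = 0.419 with an estimated correlation). The centromeric histone CenH3 was 6.11-fold higher, H2B.10 4.14-fold, H2B.6 2.32-fold and H2B.5 2.16-fold. Apart from CenH3, the members named have an H2B symbol, so the list does not stand for histones in general. Its estimated correlation was 0.336, above the preset one, so the preset test may count related members as independent. With quantile normalization H2B.5 fell under a 2-fold change (log2 0.78), and scaling by hybridisation controls brought H2B.6 to 0.38 and H2B.5 to 0.27.

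The lists for photosynthesis, cytosolic ribosomal proteins, auxin signalling, aquaporins and lignin and phenylpropanoid genes stood lower in sperm than other genes did. Photosynthesis was lower for 23 of 24 genes (adjusted p = 8.87e-05, and adjusted p = 0.211 with an estimated correlation). Cytosolic ribosomal proteins were lower for 22 of 25 genes and higher for 1 (adjusted p = 0.000174, and adjusted p = 0.248 with an estimated correlation). RPL3 and RACK1B, a scaffold protein of the small subunit, were at least 113- and 23.8-fold lower, and RPL9 was 87.8-fold lower. Without CL18 and CL27, symbols that name plastid ribosomal proteins, 20 of 23 genes were lower and 1 higher (adjusted p = 0.00024). Auxin signalling was lower for 44 of 57 genes and higher for 3 (adjusted p = 0.00464, and adjusted p = 0.267 with an estimated correlation). The repressors IAA13, IAA17 and IAA30 were at least 111-, 270- and 64.6-fold lower. Aquaporins were lower for 19 of 25 genes and higher for 2 (adjusted p = 0.0104, and adjusted p = 0.317 with an estimated correlation). The plasma membrane channels PIP1-2, PIP2-2 and PIP1-1 were at least 329-, 242- and 229-fold lower. Lignin and phenylpropanoid genes were lower in 24 of 30 cases and higher in 1 (adjusted p = 0.0192, and adjusted p = 0.211 with an estimated correlation), with PAL, the entry enzyme of the pathway, the chalcone synthase CHS and the laccase LAC7 at least 252-, 242- and 31.0-fold lower. Adjusted over the list alone, 25 members of this last list were lower and 2 higher; in the other lists of this contrast given here these counts equalled those over all genes.

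At the level of the whole array, 25169 of 57258 probe sets (44.0%) passed the threshold of limma between sperm and seedling, 11038 of them higher in sperm and 14131 lower. The arrays of the groups did not overlap at 55.8% of probe sets, where chance gives 10%. Of 17905 genes, 4340 were higher and 8854 lower, and 137 of 3444 genes with several probe sets had calls in both directions. Scaling by ribosomal protein probe sets assumes those transcripts to be constant, although their list was called lower than other genes in this contrast. It turned the counts to 36648 higher and 4914 lower. The share of calls that were higher was 43.9% at the authors' scaling, 48.2% by median and 52.5% by quantiles. The share of changes in each direction thus rests on the scaling. The list for histones was no longer called with quantile normalization (adjusted p = 0.0612), ribosomal scaling (0.0525) or hybridisation scaling (0.124), within a range of 0.00655 to 0.419 over its alternatives.

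Pollen was next compared with seedlings, which describes a sample made up mainly of the vegetative cell. CIPK30 (LOC4325611), a kinase that binds calcium sensors, had a mean signal of 64808 ± 5586 (SD, n = 3) in pollen and 1.74 ± 0.088 in seedling, at least 668-fold higher in pollen (log2 change 13.35 ± 0.20, adjusted p = 6.25e-14). The calcium-dependent kinases CPK2 and CPK29 were at least 613- and 894-fold higher. The wall-loosening expansins EXPA32, EXPB10 and EXPB9 were at least 735-, 959- and 1103-fold higher. The actin-binding proteins VLN4, a villin, and ADF9, an actin-depolymerizing factor, were at least 617- and 677-fold higher, the aldolase AldC-alpha 991-fold and the sugar transporter SWEET5 845-fold. Among the largest decreases, BURP17 was at least 159-fold lower (log2 change −10.92 ± 0.60, adjusted p = 4.86e-09), 2-HPCL 138-fold, petC 312-fold and the homeobox gene HOS59 178-fold. The peroxisome gene PEX11-1, the plastocyanin PETE, BURP2, MT-1-4b, the chlorophyll pathway reductase CHLP and the allene oxide cyclase aoc, an enzyme of jasmonate synthesis, were each at least 71.2-fold lower.

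The lists for photosynthesis, cytosolic ribosomal proteins, lignin and phenylpropanoid genes and auxin signalling also stood lower in pollen than other genes did, while aquaporins were not called (adjusted p = 0.540). Photosynthesis was lower for 22 of 24 genes (adjusted p = 0.00016, and adjusted p = 0.211 with an estimated correlation), with the light-harvesting gene CAB2R at least 402-fold lower. Cytosolic ribosomal proteins were lower for 22 of 25 genes (adjusted p = 0.000525, and adjusted p = 0.267 with an estimated correlation). RPS4 was 65.9-fold lower, RPL9 49.3-fold and RPL10A 43.5-fold. Without CL18 and CL27, 20 of 23 genes were lower (adjusted p = 0.000834). Lignin and phenylpropanoid genes were lower in 23 of 30 cases (adjusted p = 0.0127, and adjusted p = 0.211 with an estimated correlation), with CHS 163-fold lower and the laccases LAC7 and LAC3 at least 31.0- and 9.67-fold. Auxin signalling was lower for 43 of 57 genes and higher for 5 (adjusted p = 0.0257, and adjusted p = 0.350 with an estimated correlation), IAA17 by 188-fold and IAA21 and the response factor ARF12 by at least 72.7- and 29.6-fold; the mean change of this list, −2.93 on the log2 scale, moved with all genes to 0.07 under scaling by ribosomal proteins, where the list was still called lower than other genes (adjusted p = 0.0029). Adjusted over the list alone, 24 lignin genes were lower, and 44 auxin genes were lower and 6 higher. The auxin call was lost without seedling replicate 1 (adjusted p = 0.0533), 2 (0.0601) or 3 (0.0615) and with hybridisation scaling (0.113), in a range of 0.0029 to 0.350 over its alternatives.

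In all, 28214 probe sets (49.3%) passed the threshold of limma between pollen and seedling, 14845 higher in pollen and 13369 lower, and 61.9% of probe sets had arrays that did not overlap, where chance gives 10%. The direction differed by annotation: of 17905 genes, 3862 were higher and 8798 lower. Of 3444 genes with several probe sets, 218 had calls in both directions. These counts moved most with scaling, to 42968 higher and 4197 lower by ribosomal protein probe sets and to 5028 and 20189 by hybridisation controls, the latter chosen after seeing the data.

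Sperm cells were then compared with whole pollen, which itself contains sperm cells. GLT2 (LOC4339561), a glutamate synthase, had a signal of 2407 ± 320 (SD, n = 3) in sperm and 39.0 ± 43.9 in pollen, at least 24.8-fold higher in sperm (log2 change 6.36 ± 0.62, adjusted p = 1.67e-06). The meiotic recombinase gene DMC1 was 57.3-fold higher and PP2C58, a protein phosphatase, 49.0-fold. The metal pump HMA2, the homeobox gene HOX4, the glutamate receptor-like gene GLR3.1, MADS50, the bZIP factor ABF2, the β-glucosidase BGLU7 and EDR1-like were each at least 8.71-fold higher. The jasmonate receptor gene COI1 had a signal of 34.6 ± 18.9 in sperm and 19916 ± 2550 in pollen, at least 205-fold lower in sperm (log2 change −9.12 ± 0.31, adjusted p = 6.20e-11). IMCE was at least 427-fold lower, the glutamate dehydrogenase GDH2 394-fold, actin-6 304-fold and the magnesium transporter MRS2-A 292-fold. The bZIP gene BZIP02, the arsenate reductase ACR2.2, the cytokinin-activating enzyme gene LOGL7, the kinase CIPK19 and the phosphatase PP2C78 were at least 64.2-fold lower.

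Histone, small RNA, DNA replication and DNA methylation genes stood higher in sperm than in pollen. All 6 histone genes were higher (camera, adjusted p = 0.00464, and adjusted p = 0.350 with an estimated correlation), CenH3 by 20.6-fold, H2B.6 by 16.8-fold, H2B.10 by 13.2-fold and H2B.7 by 13.2-fold. Here too the members named are CenH3 and genes with an H2B symbol, and the estimated correlation of the list was 0.336. The preset test may therefore count related members as independent. Of 26 small RNA pathway genes, 21 were higher and 2 lower (adjusted p = 8.87e-05, and adjusted p = 0.211 with an estimated correlation). AGO14 was 24.2-fold and AGO17 20.1-fold higher, and AGO1D and AGO1 were at least 7.76- and 13.6-fold higher. Of 30 DNA replication genes, 21 were higher and 3 lower (adjusted p = 0.000525, and adjusted p = 0.211 with an estimated correlation). The helicase subunits MCM3 and MCM2 were 33.3- and 33.7-fold higher, RPA32 was 35.7-fold higher and ORC1 at least 12.5-fold. Of 6 genes for DNA methylation and demethylation, 5 were higher and none lower (adjusted p = 0.0257, and adjusted p = 0.373 with an estimated correlation). The maintenance methyltransferase gene MET1-2 was 26.4-fold higher, the demethylase DNG701 12.2-fold, DRM2, a de novo methyltransferase, 8.86-fold and MET1-1 at least 2.25-fold. Aquaporins were lower in sperm for 10 of 25 genes and higher for 1 (adjusted p = 0.0406, and adjusted p = 0.350 with an estimated correlation), SIP2-1 by 196-fold, TIP2-2 by 147-fold and TIP2-1 by 142-fold, and TIP4-1 by at least 98.0-fold. Adjusted over the list alone, 11 aquaporin genes were lower.

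Between sperm and pollen, 22860 probe sets (39.9%) passed the threshold of limma, 9738 higher in sperm and 13122 lower. Arrays did not overlap at 50.2% of probe sets, where chance gives 10%. Of 17905 genes, 5209 were higher and 5007 lower, and 137 of 3444 genes with several probe sets had calls in both directions. Scaling to the same median brought the count of lower probe sets to 8397 and scaling by hybridisation controls to 7960. The aquaporin call was lost in 9 of 25 alternatives, among them quantile normalization (adjusted p = 0.101) and the fits without seedling replicate 2 (0.0507), without seedling replicate 3 (0.0501) and without pollen replicate 2 (0.0560), in a range of 0.0219 to 0.350; the DNA methylation call was lost with hybridisation scaling (0.0605) and with the mean of all probe sets of a gene (0.138), in a range of 0.0170 to 0.373.

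Transcripts preferential to 1 of the male samples were those past the threshold against both other groups. Sperm cells had 5946 such probe sets (10.4%), which covered 2769 genes. The probe set count lay between 4791 and 9064 over the alternatives. DMC1 had a signal of 13971 ± 4234 (SD, n = 3) in sperm, 244 ± 112 in pollen and 122 ± 23.9 in seedling. Replication and division genes were among the 10 named, with ORC3 31.8-fold over pollen and 53.5-fold over seedling, RPA32C 28.0- and 61.6-fold, the B-type cyclin CycB1-1 (LOC4326914) 28.7- and 69.3-fold, and NEK1 32.1- and 277-fold. PSS1, a kinesin gene known from pollen semi-sterility, was 31.2- and 49.4-fold higher and the calcium pump ACA8 28.2- and 49.9-fold. GLT2 was at least 24.8-fold higher than in either group. The metal transporter MTP7 and the anther gene MIL2 were 43.1- and 39.6-fold over pollen and at least 59.3- and 82.3-fold over seedling.

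Pollen had 7438 preferential probe sets (13.0%) in 2215 genes. IMCE had a signal of 41477 ± 3395 in pollen, 82.1 ± 23.6 in sperm and 77.6 ± 12.1 in seedling. Wall and cytoskeleton genes were again among the 10 named, with EXPA26 276-fold over sperm, EXPB10 272-fold and ADF6 206-fold. The calcium genes CPK2 and CML32 were 191- and 211-fold over sperm and CPK6 at least 140-fold. The signal peptide peptidase-like gene SPPL3 was 268-fold over sperm. The yellow stripe-like transporters osysl4 and osysl8 were 176-fold and at least 118-fold over sperm. Scaling to the same median reduced the pollen count to 4558 and scaling by hybridisation controls to 2863, while ribosomal scaling raised it to 12837. In seedling, 9862 probe sets in 6687 genes were higher than in both male samples.

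**Figure D1:**
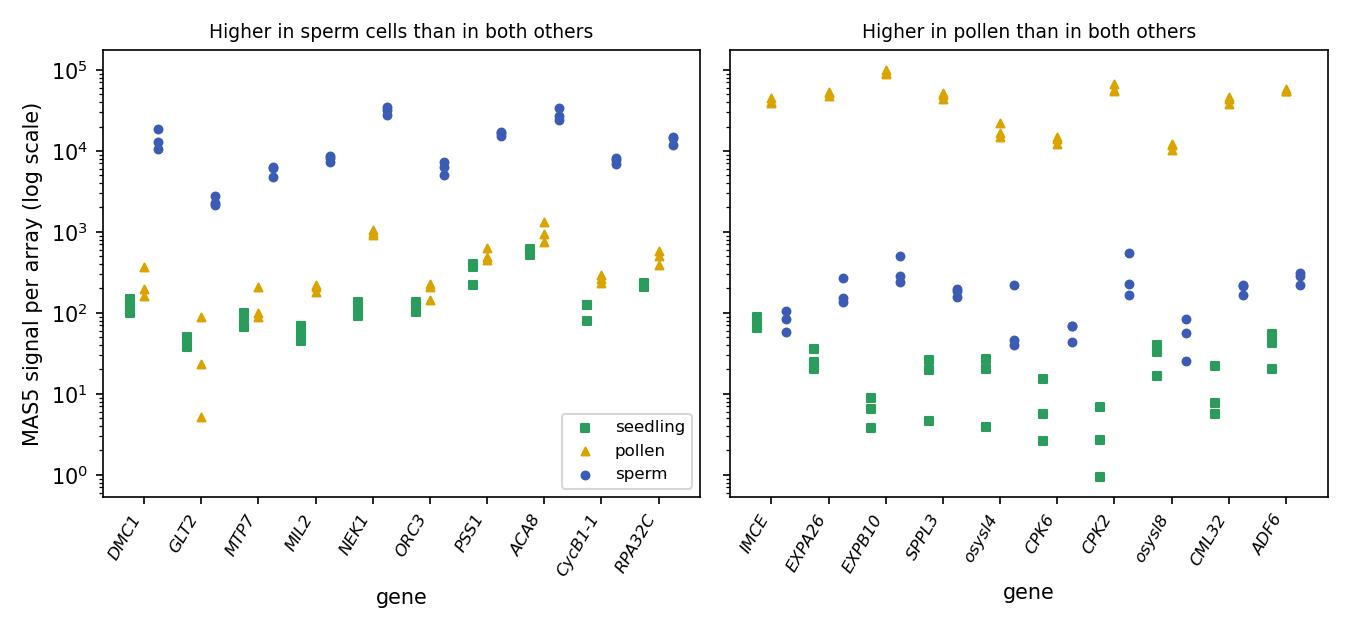
MAS5 signal on each array (log scale, 1 point per array, 3 arrays per group) for the 10 named genes with the largest preferential change in sperm (left) and in pollen (right); squares are seedling, triangles pollen and circles sperm. The sperm points of DMC1 average 13971 against 244 in pollen, and the pollen points of EXPB10 average 93071 against 343 in sperm.

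The changes of sperm and pollen against seedling were set side by side to see which genes moved alike. MPK17 was at least 404-fold and EXPB9 at least 99.1-fold higher in sperm than in seedling, and MPK17 had a signal of 74032 ± 2096 (SD, n = 3) in pollen and 39247 ± 3004 in sperm. Lower in both were 2-HPCL, petC, BURP2 and MT-1-4b, each named in both contrasts. In all, 5656 probe sets were higher in both and 9862 lower in both, where independent lists of these sizes would share 2862 and 3299. Opposite calls were made at 2254 probe sets, where independent lists would give 6241. Both contrasts use the same 3 seedling arrays, which by itself makes changes correlate: across probe sets the log2 changes correlated at 0.685, and at 0.499 on average over 20 simulations of unchanged groups, which gave 0 shared calls. No probe set was given a change in these simulations, so their 0 is no baseline for shared calls between groups that differ. The covariance of the changes was 4.99, against 0.173 in the simulations. With the seedling arrays divided, 1 for a contrast and 2 for the other, a check chosen after seeing the data, the correlation lay between 0.650 and 0.656 and the covariance between 4.84 and 4.87 over the 6 divisions. A division leaves 1 contrast with a single seedling array, so shared calls were not counted anew and part of their excess may come from the shared arrays. The counts moved to 32495 higher and 2716 lower in both with ribosomal scaling, and hybridisation scaling brought those higher in both to 2204.

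**Figure D2:**
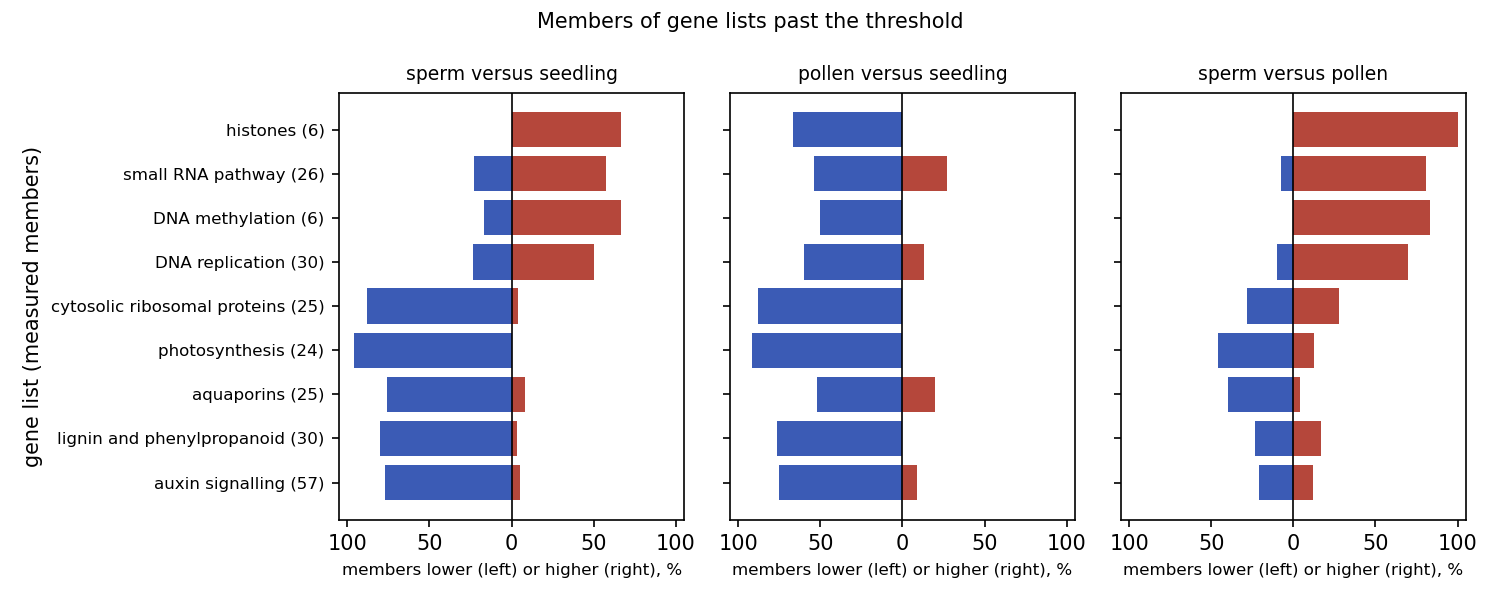
Share of the measured members of each gene list that passed the threshold of limma (in percent, higher to the right in red and lower to the left in blue) in the 3 comparisons, for the 9 lists called in at least 1 of them; the number of measured members stands beside each list. Of the 30 DNA replication genes, 15 were higher and 7 lower in sperm than in seedling, and of the 24 photosynthesis genes 23 were lower; the shares hold at the authors' scaling.

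Over all lists, 17 of 99 tests passed the threshold with the preset correlation, and 11 further tests had an unadjusted p under 0.05. With correlations estimated from 9 arrays, 0 of 99 passed and the smallest adjusted p was 0.211. A larger correlation does not account for every loss. The lignin and phenylpropanoid list had an estimate of −0.000113, below the preset correlation. Its camera adjusted p was still 0.211 in sperm and in pollen against seedling. The other called lists had estimates above the preset one, up to 0.336 for histones. What else caused the losses was not tested. The median change over all genes was −1.25 on the log2 scale for sperm against seedling, −1.19 for pollen against seedling and −0.12 for sperm against pollen, and camera's direction is relative to the other genes. In 19 of 99 tests, none of them called, the mean change of the list had the opposite sign to that direction, and in 3 of these the median also differed in sign from the mean.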

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

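No test was run on the values in this part, which were noticed after the data were seen. They come from control probe sets that the comparisons between groups do not use. A control probe set for actin of the rice blast fungus, toward the 5′ end, read 239.9 ± 124 (SD, n = 3) on the pollen arrays, from 97.4 to 325, against 13.3 ± 8.73 on the seedling arrays, a value under the background limit. A control probe set for elongation factor 1α of the same fungus, at the 3′ end, read 784.9 ± 174 on the pollen arrays, from 667 to 984, against 7.96 ± 1.66 on the seedling arrays, again under that limit. The means of the other fungal control probe sets in pollen stayed under the background limit of 97.1, among them a second probe set for the 3′ end of elongation factor 1α, with a suffix that marks possible cross-hybridisation, at 37.8 ± 13.7. The highest of them was 81.9 ± 46.4 for the middle of actin, with 47.6 ± 48.1 for the 5′ end of the glyceraldehyde phosphate dehydrogenase gene, 19.7 ± 2.20 for the middle and 7.44 ± 3.61 for the 5′ end of elongation factor 1α, 4.81 ± 2.16 for the 3′ end of actin, and 43.6 ± 30.5 for the 3′ end and 10.4 ± 9.87 for the middle of the dehydrogenase gene.

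The poly-A transcripts added to the RNA before labelling averaged 11199 ± 12376 over their 3′ probe sets on the sperm arrays, from 3755 to 25486, against 987 ± 198 on the seedling arrays, a ratio of 11.4. On the pollen arrays they averaged 1083 ± 194. Relative to the hybridisation controls of the same arrays, they stood at 1.56 ± 1.33 in sperm, 0.117 ± 0.017 in pollen and 0.298 ± 0.087 in seedling. The highest sperm value belongs to replicate 3, which raises both sperm means. Replicates 1 and 2 read 3755 and 4357, or 0.753 and 0.833 relative to the hybridisation controls. Without replicate 3, the counts of the sperm contrasts stayed within 1.5 times those given.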

How the results depend on the processing

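Scaling by hybridisation controls, the filter at the background limit and the ribosomal protein list and scaling without CL18 and CL27 were chosen after seeing the data; the rest had been fixed before. Array scaling set the balance of directions. It moved the median log2 change of all probe sets for sperm against seedling, pollen against seedling and sperm against pollen from 0.03, 0.52 and −0.48 to 2.18, 2.75 and −0.56 by ribosomal protein probe sets, 2.03, 2.53 and −0.49 by these without CL18 and CL27, −0.61, −0.63 and 0.01 by hybridisation controls, 0.20, 0.20 and 0.01 by median and 0.22, 0.29 and −0.04 by quantiles. The share of calls that were higher moved from 43.9%, 52.6% and 42.6% to 88.2%, 91.1% and 40.6% by ribosomal proteins, 86.6%, 89.3% and 42.5% by these without CL18 and CL27, 28.9%, 19.9% and 60.03% by hybridisation controls, 48.2%, 41.9% and 59.7% by median and 52.5%, 51.5% and 53.6% by quantiles. Counts beyond 1.5 times those given were, by ribosomal proteins, 36648 higher and 4914 lower in sperm than seedling, 42968 and 4197 in pollen than seedling, 12837 preferential to pollen, and 32495 higher and 2716 lower in both. By ribosomal proteins without CL18 and CL27 they were 34766 and 5400, 40912 and 4880, 12198 preferential to pollen, 9064 to sperm, and 29992 and 3141 in both. By hybridisation controls they were 5028 higher and 20189 lower in pollen than seedling, 7960 lower in sperm than pollen, 2863 preferential to pollen and 2204 higher in both. By median they were 8397 lower in sperm than pollen and 4558 preferential to pollen. With only means above the median, which drops the dim part of the probe sets, 9372 were higher in pollen than seedling. An estimated correlation left 0 list calls. Apart from construction (fewer probe sets tested), the cause was not tested. Leaving out 1 array gave 10105 to 11223 higher and 13163 to 14334 lower in sperm than seedling, 12586 to 14792 and 12530 to 13430 in pollen than seedling, 9102 to 9630 and 11529 to 12464 in sperm than pollen, 5532 to 5912 preferential to sperm, 6500 to 6868 to pollen, 5093 to 5458 higher and 9061 to 9775 lower in both, and 15 to 18 list calls. Of 152 changes of named genes, none changed sign, while H2B.5 and H2B.6 in sperm against seedling fell under the threshold as reported. Without probe sets of cross-hybridising suffixes only 141 of the 152 could be compared, because examples from called lists were not filtered by suffix. The 152 were picked for their size and leave out the examples dropped from lists not called. Their count therefore does not extend to other changes. Among 1598 called changes of members of lists not called, 307 changed sign by ribosomal proteins, 260 by these without CL18 and CL27, 19 by hybridisation controls and 2 by quantiles. Of these 1598, 287 rank among the 4 largest of a list and fall outside the rule for named genes; 17, 14, 1 and 0 of them did. List means changed sign in 44, 14, 10 and 7 of 99 tests by ribosomal proteins, hybridisation controls, median and quantiles. The first 3 multiply a whole array by 1 factor, so these changes follow the shift of all genes. The only one in a called test was auxin in pollen, which stayed called. Without CL18 and CL27 the ribosomal scaling gave 40, none in a called test. DNA repair in sperm against seedling was called in 7 of 25 alternatives and cellulose and glucan synthesis in 10. DNA repair in sperm against pollen, expansins in sperm and in pollen against seedling, and cellulose and glucan synthesis in pollen against seedling were called in 2, and heat shock proteins and MADS-box factors in pollen against seedling in 1. Signal over background limits the counts: of 11038 probe sets higher in sperm than seedling, 8919 had a group mean above the background limit, and of 14845 in pollen, 10485.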

Other observations

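The tests on splits of 6 arrays and on transcripts shared by pollen and sperm, the grouping of the splits of 9 arrays by their make-up and the background ratios without seedling replicate 2 were chosen after the results they measure were seen; for the count over splits of 9 arrays and for probe sets without a listed gene, what each test would show was written before it was run. In pollen, the expansin, actin, calcium and sugar lists each held genes with large increases over seedling, and none of these lists was called, although expansins passed the threshold, as lower than other genes, under both ribosomal scalings. Of 29 expansin genes, 4 were higher in pollen than in seedling, EXPA32, EXPB10, EXPB9 and EXPA26, by at least 735-, 959-, 1103- and 524-fold, and 20 were lower (adjusted p = 0.348). Of 28 actin cytoskeleton genes, 9 were higher, VLN4, ADF9 and ADF6 the most, and 17 lower (adjusted p = 0.964). Of 88 calcium signalling genes, 23 were higher, CIPK30, CPK2 and CPK29 the most, and 47 lower (adjusted p = 0.823). Of 48 sugar transport and starch genes, 16 were higher, SWEET5 the most, and 25 lower (adjusted p = 0.702). Under ribosomal protein scaling, which moved the median of all probe sets from 0.52 to 2.75, the mean log2 changes of these 4 lists moved with it from −1.54, −0.46, −0.66 and −0.94 to 1.32, 2.47, 2.30 and 2.14. In sperm, these families had 4 higher and 20 lower, 7 and 13, 15 and 47, and 15 and 25 genes against seedling, and 2 and 8, 8 and 10, 24 and 34, and 15 and 17 genes against pollen.

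The lists for cell cycle, kinesins, DNA repair, proteasome and histone modifiers held a mixed pattern in sperm, and none was called in the main tests. Of 36 cell cycle genes, 18 were higher in sperm than in pollen, NEK1 among them, and 6 lower (adjusted p = 0.171), while against seedling 12 were higher and 16 lower and in pollen against seedling 8 and 19. Kinesins had 16 of 32 members higher in sperm than in pollen and 6 lower (adjusted p = 0.246), 9 and 16 against seedling, and 3 and 21 in pollen against seedling. DNA repair had 12 of 21 members higher in sperm than in pollen, DMC1 among them, and 4 lower (adjusted p = 0.126), 10 and 5 against seedling (adjusted p = 0.0537), and 8 and 9 in pollen against seedling. Proteasome subunits had 11 of 16 members higher in sperm than in pollen and 5 lower (adjusted p = 0.171), 6 and 6 against seedling, and 1 and 6 in pollen against seedling. Histone modifiers had 9 of 22 members higher and 6 lower in sperm than in pollen, 8 and 9 against seedling, JMJ705 among them, and 5 and 8 in pollen against seedling.

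Markers of anther wall cells that a pollen sample can carry, 11 genes of the tapetum list, had 2 higher and 1 lower in pollen than in seedling (adjusted p = 0.540), 2 and 3 in sperm than in seedling, and 1 and 4 in sperm than in pollen. Heat shock proteins, which respond to handling, had 4 of 32 members higher and 21 lower in pollen than in seedling (adjusted p = 0.158), 2 and 20 in sperm than in seedling (adjusted p = 0.170), and 6 and 10 in sperm than in pollen. Higher and lower members in sperm against seedling, pollen against seedling and sperm against pollen were, in this order, 3 and 15, 2 and 13, and 6 and 7 of 21 for ubiquitin conjugation. They were 0 and 8, 1 and 8, and 3 and 4 of 10 for small GTPase signalling. They numbered 4 and 6, 2 and 7, and 4 and 2 of 12 for vesicle trafficking, and 5 and 31, 3 and 28, and 7 and 12 of 43 for cellulose and glucan synthesis. Potassium transport had 5 and 14, 8 and 16, and 5 and 8 of 28. The regulators gave 5 and 4, 9 and 5, and 5 and 7 of 31 for MADS-box factors, 2 and 7, 1 and 6, and 3 and 1 of 10 for MYB factors, and 0 and 5, 1 and 5, and 2 and 2 of 6 for WRKY factors. Homeobox and WOX factors had 3 and 28, 6 and 31, and 10 and 14 of 51. Jasmonate signalling had 3 and 16, 6 and 16, and 3 and 10 of 29, phosphatase 2C 14 and 29, 15 and 28, and 19 and 18 of 55, CCCH zinc finger proteins 18 and 20, 11 and 21, and 20 and 11 of 50, and autophagy 3 and 2, 1 and 2, and 3 and 1 of 7. None of the 82 tests not called, which include all of these 24 lists, had an adjusted p under 0.0531. For lists called elsewhere, pollen against seedling gave 0 and 4 of 6 histone, 7 and 14 of 26 small RNA, 0 and 3 of 6 DNA methylation, 4 and 18 of 30 DNA replication and 5 and 13 of 25 aquaporin genes, and sperm against seedling 4 and 1 of 6 DNA methylation genes. Sperm against pollen gave 7 and 7 of 25 ribosomal protein, 3 and 11 of 24 photosynthesis, 5 and 7 of 30 lignin and 7 and 12 of 57 auxin genes. The ribosomal list had a mean of −0.27 and a median of 0.08 there. These counts hold at the authors' scaling, and adjusted over the list alone those of lists not called differed from them by at most 2.

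Transcripts higher than seedling in both pollen and sperm numbered 5656 probe sets. Pollen RNA carried into the sperm samples is one candidate explanation. It would leave sperm signals at the share of the pollen signal that abundant pollen transcripts keep. The 5th percentile of that share over 454 such probe sets bounds it at 0.251%. Of the shared probe sets, 95.8% stood above 3 times this bound on all sperm arrays. This share cannot decide the question. For dim pollen transcripts that level lies under the background limit, and the probe sets were selected as higher in sperm than in seedling. Their median sperm signal was 109.8% of pollen, with 1698 called higher in sperm than in pollen and 1251 lower. The 1698 argue against carryover as the cause for these. Among the 454 abundant pollen probe sets, 410 were still called higher in sperm than in seedling, at a median of 0.938% of pollen. Of these, 48.8% stood above the same level on all sperm arrays, short of the majority set for excluding carryover, which stays open there. The reverse is sperm transcripts measured inside whole pollen. The share that 83 abundant sperm probe sets keep in pollen bounds it at 2.23%. Of the shared probe sets, 92.9% stood above 3 times this bound on all pollen arrays, a share with the same limit. Their median pollen signal was 91.1% of sperm, with 1251 lower in sperm than in pollen and 1698 higher. The 1251 argue against this explanation as the cause of the whole overlap. For part of the overlap it stays open: of 2396 sperm-preferential probe sets dim in seedling, 38.6% were higher in pollen than in seedling, at a median over the 2396 of 13.9% of the sperm signal, against 30.5% of all probe sets dim in seedling. A male program shared by both cells, which the design names, was not tested by itself.

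Among calls for pollen against seedling, 76.0% were higher where the annotation lists no gene and 31.9% where it lists 1, a difference of 44.1 percentage points. The difference was 38.4 points over probe sets above the background limit, which argues against signals near background as its whole cause. It was 47.6 points without probe sets of several targets, which argues against these. A higher background on the pollen arrays may contribute: over controls with no rice target, the pollen arrays read 1.05, 1.499 and 1.67 times the highest seedling array. Under 1.5 on every pollen array had been set for excluding it and at least 2 on every one for accepting it, so this cannot be told apart from transcription of unlisted genes in pollen. Seedling replicate 2 sets this outcome: without it the ratios were 2.48, 3.54 and 3.93, past the level for accepting. Sperm against seedling, looked at after these results were seen, had a difference of 26.0 points, and 24.2 points over probe sets above the background limit, so the difference was not limited to pollen. Over the same controls, the sperm arrays read 0.635, 0.882 and 0.336 times the highest seedling array. Without seedling replicate 2 these ratios were 1.498, 2.08 and 0.793, so a raised background was not seen on every sperm array. Transcription of unlisted genes was not tested.

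With 10 splits of the 6 arrays of a contrast, no share under 0.05 can be reached; the real split gave 25169, 28214 and 22860 calls, and the highest other split gave 0 in each, so 1 of 10 splits reached the real count. Over 100 splits of the 9 arrays, 1 gave as many probe sets higher in 1 group than in both others as the real 23246. This was the real split itself, and the highest other gave 7717. For same-way calls, 1 gave as many as the real 38675, with 10818 the highest other. Every other split mixes arrays of the real groups, which puts their differences into the spread and lowers both counts. The lead of the real split therefore shows only that the arrays differ by group, and not what made them differ. For the 17 list calls these splits cannot exclude chance: 23 of 100 gave as many, the highest 33. The count cannot speak for chance either, because 88 other splits keep part of the differences between groups, and 22 of these gave as many. In 11 splits every part held 1 array of each real group, so the group differences fell within parts. These gave at most 2 list calls, and why they gave fewer was not tested.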
